A study of Mus musculus with 16 samples.

How the data were processed

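Gene expression was measured in CD4 T cells sorted from the spleens of 6 week old NOD/LtJ mice, on 16 Affymetrix arrays whose probes are all perfect matches. The labels place 4 arrays in each of 4 groups, which are regulatory T cells (Tregs) and conventional T cells (Tconv) from WT mice, which carry the Foxp3 reporter transgene Tg(Foxp3-EGFP/cre)1aJbs, and from KI mice, which carry the knock-in allele Foxp3tm2Ayr. The labels do not say whether the arrays of a group came from separate mice, so each p-value measures only the spread between these samples. The protocol in the labels gives a gate of CD3 and CD4 without GFP for every sample, those labelled as Tregs included, so the gate of the Tregs is unclear. Foxp3 averaged 9.86 and 9.76 in the samples labelled as WT and KI Tregs and 4.63 and 3.69 in Tconv. Per the labels' protocols, cells were lysed directly after sorting, RNA was isolated with TRIZOL, and biotinylated cRNA was prepared by the Affymetrix 3' IVT Express protocol.

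The deposited values are log2 expression values per probe set, which per the submitters' processing notes the authors made with RMA in Partek 6.5. RMA subtracts background, equalises the distributions of the arrays and summarises the probes of each probe set. Its options were not stated. The values ran from 1.95 to 13.9, and the array medians from 3.69 to 3.76. The 23 control probe sets with no specific target had a median of 2.60 and a highest value of 4.71, so values under about 5 lie near background and differences there understate the true fold. The number of arrays limits the precision.

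The table held 45141 probe sets, of which 104 were controls, 28898 matched 1 gene, 551 matched several and 15588 had no listed gene. Among those with 1 gene, 28689 were matched by Entrez identifier and 152 by symbol, and 57 kept the symbol of the array annotation. Each of the 17097 genes was represented by the probe set with the highest mean over all 16 arrays. Genes with a log2 value above 5 on at least 4 arrays were kept, which left 8139 genes.

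A model with 1 mean per group was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3, with moderated variances that followed a trend on mean expression. The comparisons were Tregs against Tconv within each genotype, KI against WT within each cell type, and the interaction, which is the KI minus WT difference in Tregs less that in Tconv. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 8139 genes, and a gene passed at an adjusted p under 0.05. Values are given as log2 differences with the standard error (SE) of limma, or as group means with the SD over 4 arrays. The mean of the genotype differences in both cell types was also tested, a contrast added after the data were seen. The share of the WT Treg difference that the KI cells showed was computed without a test. For each of 36 ways to choose 2 WT arrays of each cell type, genes that differed by at least 1 (log2) in them were selected, and their median difference in the 8 KI arrays was divided by that in the remaining WT arrays.

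Before the data were examined, 28 gene lists were fixed from general knowledge, together with the comparisons, the tests, the rule for naming genes and the alternatives, apart from those said below to be added later. The lists covered genes higher or lower in Tregs, Foxp3 partners and chromatin regulators, the effector Treg program, the resting and lymphoid homing program, helper cytokines, the IL-2 and STAT5 pathway, glycolysis and HIF targets, apoptosis, the cell cycle, the interferon response, the immediate response to T cell receptor (TCR) signals, chemokine receptors and adhesion, coinhibitory receptors and oxidative phosphorylation. They also covered markers of B cells, plasma cells, monocytes, neutrophils, dendritic cells, CD8 T cells, NK cells, erythroid cells, platelets and stroma, heat shock genes, sex markers and the neighbours of Foxp3 on the X chromosome. Of these, 25 had at least 2 tested genes. Each was compared with all other genes by camera in limma with a preset correlation of 0.01, with the Benjamini-Hochberg method over the lists of a comparison. The same test was run with a correlation estimated from the data. Fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes, was run beside it. Scores of the marker lists, the mean log2 value per array, were compared between 2 groups by a two-sided exact permutation test over 70 assignments, for which the smallest p is 0.0286.

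The genes named are, for each comparison, the 6 largest rises and the 6 largest falls among genes that passed and whose arrays did not overlap between the groups (no such condition for the interaction), up to 4 members of each list with the lowest p between KI and WT Tregs, for both Treg lists also between WT Tregs and WT Tconv, and a fixed set that held Foxp3, Il2ra, Ctla4, Ikzf2, Ikzf4, Hdac7, Irf4, Nrp1 and Tnfrsf18, and 1 more gene that was matched to no probe set and was not analysed here. Any other gene named is said to have been chosen after its values were seen. Symbols of unnamed transcripts were counted and not named by this rule.

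The titles carry numbers that run from 4 to 27, which no label explains. Taken as an order of processing, they form 2 runs (4 to 9 and 13 to 27) or 3 runs (4 to 9, 13 to 23 and 24 to 27). The first run holds WT arrays, the second run of the 3 holds KI arrays, and only the arrays numbered 24 to 27, 1 of each group, hold both genotypes, so a run effect and the genotype are largely confounded. Values with the runs as fixed blocks, with the runs as a random block and within the arrays numbered 24 to 27 are given beside the genotype comparisons. Other settings fixed with the lists were no filter or a filter at log2 7, all probe sets tested separately, a median shift or quantile normalization, no variance trend, array weights, a fit of the compared groups alone, an added threshold of 1.5-fold, and leaving out each array in turn. Added after the data were seen were fits without the arrays numbered 24 to 27, fits with neutrophil, erythroid and B cell marker scores as covariates, and list tests with these fits or with the runs as blocks. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.

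The procedure was tested on simulated data with the spread of these arrays. Of 67 genes changed 1.5-fold between KI and WT Tregs 46 passed in the right direction, of 67 changed 2-fold 66 did, and of 66 changed 4-fold all did. Of the unchanged genes 7 passed. The simulated noise was drawn for each gene on its own, without runs, cells of other types or ties between genes. The 7 therefore do not give the rate of false calls in the real arrays. Probe sets with several genes were left out. Positions on the genome were used only to tell which genes are neighbours, in assembly GRCm38.p6.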

Results

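Tregs, the CD4 T cells that depend on the transcription factor Foxp3 and restrain immune responses, and Tconv were profiled from the spleens of NOD/LtJ mice of a pair of genotypes. WT mice carried a transgene that expresses a fusion of EGFP and Cre under Foxp3 control, and KI mice carried a knock-in allele at Foxp3 itself. The labels describe the KI samples as Foxp3gfp. The series title raises the question of what an altered Foxp3 does to chromatin-dependent gene control and to Treg function. Each of the 4 groups had 4 arrays, and between 17581 and 17990 probe sets per array lay above a log2 value of 5.

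The arrays separated first by cell type. The first principal component, which split Tregs from Tconv, held 69.9% of the variance. The second held 7.83% and over the 16 arrays correlated with the B cell (0.854), neutrophil (0.835) and monocyte (0.784) marker scores. The third held 7.17%. On it the KI arrays numbered 13 to 23 lay at 3.93 to 21.0. KI Treg 4 (-8.17) and KI Tconv 4 (-2.36) lay within the range of the WT arrays, -12.4 to 1.61. Across genes, which are not independent replicates, arrays of the same group correlated at 0.976 to 0.996, and Treg arrays with Tconv arrays at 0.908 to 0.952. Xist, the transcript of the inactive X chromosome, ranged from 11.7 to 12.2, while no Y-linked gene of the sex list exceeded 3.08 on any array.

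WT Tregs carried the transcripts that define the lineage. Il2ra, the alpha chain of the IL-2 receptor, was 45.1-fold higher in WT Tregs than in WT Tconv (log2 difference 5.50, SE 0.132, n = 4 and 4, limma adjusted p = 2.25e-15). Foxp3 was 37.6-fold higher, at 9.86 ± 0.20 against 4.63 ± 0.32 (SD, n = 4). Il2ra (3.80) and Foxp3 lay near background in WT Tconv, so these folds are understated. The other largest rises were in Plagl1 (5.05), Penk (4.14), which encodes an opioid precursor, Cd83 (4.09) and the inhibitory receptor Ctla4 (4.08). The largest falls were in Pdlim4 (-6.05), Atp8b4 (-4.67), Lypd6b (-4.46), the phosphodiesterase gene Pde3b (-4.07), Vipr1 (-3.99) and the NK cell receptor gene Klrd1 (-3.88). In total 2818 of 8139 genes passed, 1360 higher and 1458 lower in Tregs, of which 1098 differed by at least 1.5-fold.

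All 29 tested genes of the list of genes higher in Tregs rose in WT Tregs, over all genes and adjusted over the list alone, with a mean of 3.10 (camera adjusted p = 1.73e-38). They included the transcription factor genes Ikzf2 (3.45) and Ikzf4 (3.67), Tnfrsf4 (3.41), Nrp1 (3.30) and Tnfrsf18 (1.46). Of the 12 tested genes of the list of genes lower in Tregs, 8 fell, among them Igfbp4 (-3.15), Tgfbr3 (-2.10) and Themis (-1.75), and 2 rose, with the same counts adjusted over the list alone (adjusted p = 3.09e-05). The 2 that rose were Id3 (1.42), which encodes an inhibitor of E proteins, and Ptpn22 (0.33), a phosphatase gene, and Ptpn22 was chosen after its values were seen. Of 20 effector Treg genes, a program driven by IRF4 and BATF, 19 rose and Id2 fell (-1.51, chosen after its values were seen), again with the same counts adjusted over the list alone (adjusted p = 1.54e-17). Irf4 itself rose by 1.93. Of 7 coinhibitory receptors 6 rose, by either adjustment (adjusted p = 3.09e-05), and of 16 IL-2 and STAT5 genes 9 rose and 1 fell, or 10 and 1 adjusted over the list alone (adjusted p = 4.12e-05). These 5 lists also passed with an estimated correlation.

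Several other lists passed in WT Tregs against WT Tconv with the preset correlation alone. Of 24 Foxp3 partners and chromatin regulators 10 rose, Hdac7 (0.45, adjusted p = 0.0177) among them, and 2 fell, or 10 and 3 adjusted over the list alone (adjusted p = 0.0166, and adjusted p = 0.134 with an estimated correlation). Apoptosis regulators (10 higher and 2 lower of 17), immediate TCR response genes (7 and 1 of 18) and chemokine receptor and adhesion genes (8 and 1 of 15) had the same counts adjusted over the list alone. Their camera adjusted p were 0.0011, 0.00181 and 0.00181, and their adjusted p with an estimated correlation 0.0908, 0.35 and 0.0908. The resting program (1 higher and 5 lower of 8) and helper cytokines (4 and 1 of 7) likewise had these counts adjusted over the list alone, with camera adjusted p of 0.0328 and 0.0144, and an adjusted p = 0.155 with an estimated correlation for both. Of 22 cell cycle genes 6 rose, or 5 adjusted over the list alone (adjusted p = 0.0166, and adjusted p = 0.596 with an estimated correlation). Glycolysis (8 higher and 2 lower of 16, also adjusted over the list alone, adjusted p = 0.111), interferon (5 and 3 of 16, or 6 and 3 adjusted over the list alone, adjusted p = 0.217) and oxidative phosphorylation genes (2 of 26 lower, or 1 adjusted over the list alone, adjusted p = 0.472) did not differ from other genes by camera.

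Scores of dendritic cell, CD8 and NK cell markers separated the cell types at the smallest p the exact test can give, which adjustment over 12 scores leaves above 0.05 unless at least 7 scores reach it. In WT Tregs the dendritic cell score, which rests on Irf8 and Cst3, was higher by 1.06, the CD8 score by 1.22, and the NK cell score was -0.97 relative to Tconv, each with an exact permutation p of 0.0286 and an adjusted p of 0.0857. The CD8 score rests on Cd8a and Cd8b1. Cd8a ranged from 6.22 to 6.63 in WT Tregs and from 3.65 to 4.29, near background, in WT Tconv. Cd8b1 overlapped, at 5.99 to 6.27 and 5.75 to 6.22. Of the 6 NK cell genes 2 rose and 3 fell. In KI mice the differences of the dendritic cell, CD8 and NK cell scores were 1.25, 0.78 and -0.70, with the same exact p and adjusted p. For the dendritic cell list camera gave an adjusted p = 0.0337 in WT and 0.0373 in KI, and an adjusted p = 0.155 and 0.185 with an estimated correlation. By camera the adjusted p in WT was 0.0969 for CD8, 0.179 for NK cell, 0.65 for B cell, 0.225 for plasma cell, 0.18 for monocyte, 0.823 for neutrophil and 0.65 for erythroid markers, 0.181 for heat shock genes and 0.0778 for Foxp3 neighbours.

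**Figure D1:**
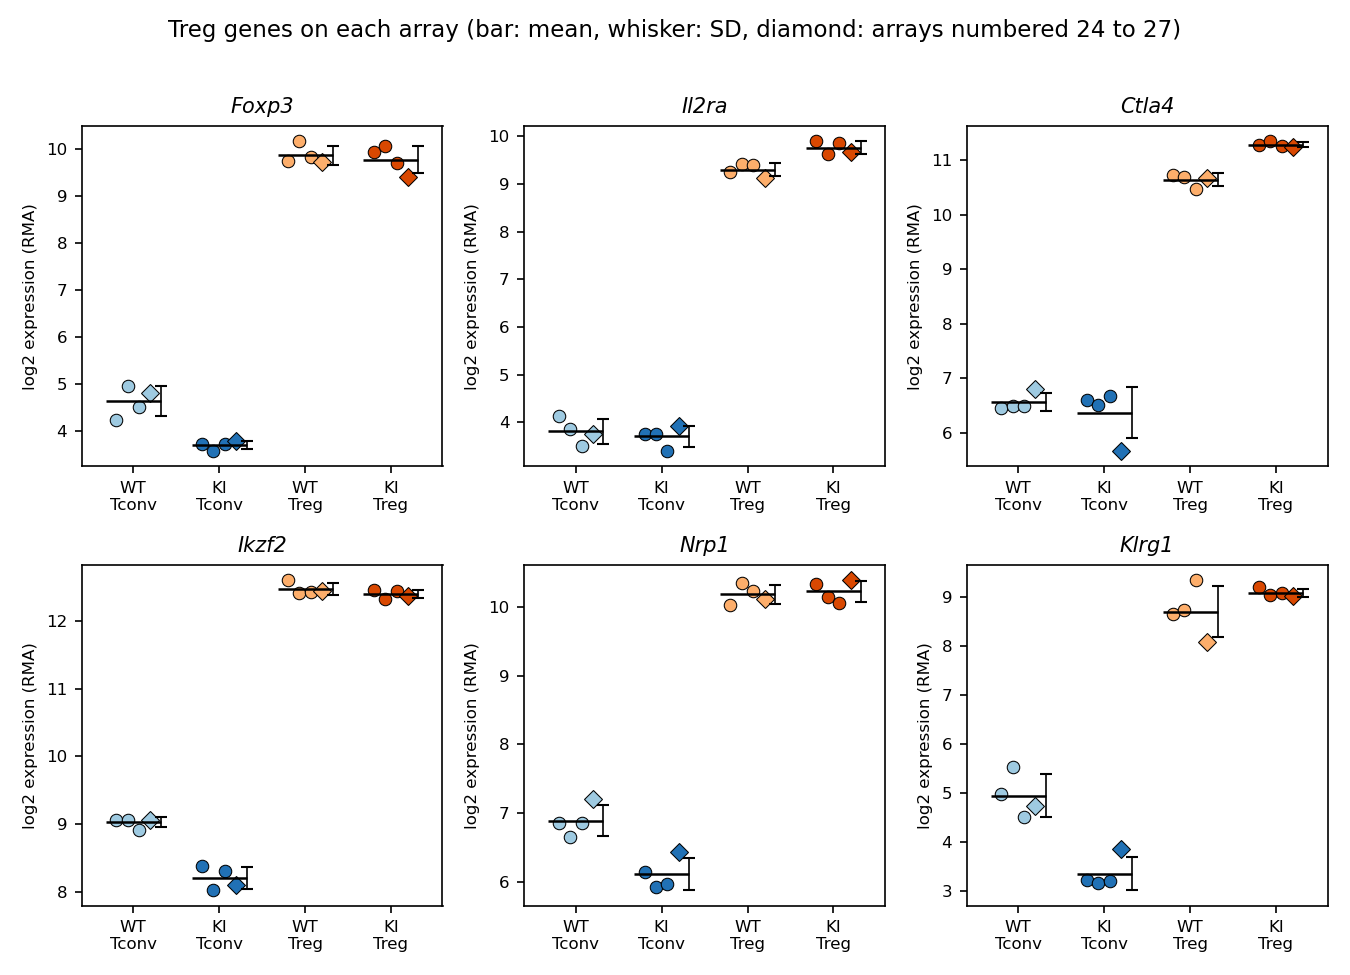
Log2 expression of 6 Treg genes on each array in the 4 groups, with the group mean as a bar and the SD as a whisker, and diamonds for the arrays numbered 24 to 27. Foxp3 averaged 9.86 in WT Tregs, 9.76 in KI Tregs, 4.63 in WT Tconv and 3.69 in KI Tconv.

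KI Tregs kept this identity. Foxp3 was 67.2-fold and Il2ra 66.9-fold higher in KI Tregs than in KI Tconv (6.07, SE 0.154, and 6.06, SE 0.132, n = 4 and 4). Both lay near background in KI Tconv (3.69 and 3.70), so these folds are understated. The next largest rises were in Klrg1 (5.73), a receptor of terminally differentiated effector cells, Ctla4 (4.91), Plagl1 (4.84) and Dusp4 (4.75), and the largest falls in Pdlim4 (-5.50), Atp8b4 (-4.71), Lypd6b (-4.70), Pde3b (-4.57), Vipr1 (-4.35) and Ggt5 (-4.20). Ikzf2 (4.20), Nrp1 (4.12), Ikzf4 (3.57), Irf4 (2.34), Tnfrsf18 (1.71) and Hdac7 (0.43) rose as well. In total 3343 genes passed, 1723 higher and 1620 lower, of which 1301 differed by at least 1.5-fold.

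The Treg lists of KI cells moved in the same direction as those of WT cells. All 29 genes higher in Tregs rose, also adjusted over the list alone (mean 3.71, adjusted p = 1.44e-35), 9 of 12 genes lower in Tregs fell and 2 rose, by either adjustment (adjusted p = 1.16e-06), and 19 of 20 effector genes rose and 1 fell, by either adjustment (adjusted p = 6.14e-18). Coinhibitory receptors (5 of 7 higher, or 6 adjusted over the list alone, adjusted p = 0.000669) also passed, and these 4 lists passed with an estimated correlation. Of 22 cell cycle genes 17 rose, or 20 adjusted over the list alone (adjusted p = 3.46e-06, and adjusted p = 0.338 with an estimated correlation). Glycolysis genes (9 higher and 3 lower of 16, by either adjustment) passed with an adjusted p = 0.00956, and adjusted p = 0.185 with an estimated correlation. With the same counts adjusted over the list alone, IL-2 (10 higher and 3 lower of 16), chemokine receptor (10 and 3 of 15), apoptosis (11 and 2 of 17), resting (1 and 6 of 8), TCR response (8 and 1 of 18) and helper cytokine genes (5 and 1 of 7) passed by camera, with adjusted p from 0.000723 to 0.0373. They did not pass with an estimated correlation, with adjusted p = 0.0871, 0.0765, 0.106, 0.0831, 0.476 and 0.246 in that order. Foxp3 partners and chromatin regulators did not pass in KI (10 higher and 5 lower of 24, by either adjustment, adjusted p = 0.0575, and adjusted p = 0.218 with an estimated correlation), and their interaction did not pass either (adjusted p = 0.985). Interferon (2 higher and 4 lower of 16, by either adjustment, adjusted p = 0.953) and oxidative phosphorylation genes (3 of 26 higher, or 1 adjusted over the list alone, adjusted p = 0.442) did not pass in KI. Hdac7, which encodes a histone deacetylase, did not pass without KI Treg 2 (0.35), KI Treg 3 (0.39) or KI Tconv 4 (0.36), nor in WT without WT Treg 2 or WT Tconv 4 (0.37 each).

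The cell types differed by much the same genes in both genotypes. Of the genes higher in Tregs 1191 were shared, against 288 for independent sets, and of those lower 1120 were shared, against 290. In opposite directions 2 genes passed, and across genes the differences correlated at 0.936. In KI cells the median difference of genes selected as higher in WT Tregs was 1.22 times that of held-out WT arrays (jackknife SE 0.064, 1.79 against 1.47, on average 410 genes). The jackknife left out KI arrays only, so the SE does not hold the spread of the WT arrays. For genes selected as lower it was 1.09 times (SE 0.020 in the same way, -1.55 against -1.43, 153 genes). Without the arrays numbered 24 to 27, genes were selected on 1 WT array of each cell type instead of 2. The ratio was then 1.27 for higher and 0.998 for lower genes. The changed selection and the missing arrays cannot be told apart there. None of these ratios tells a change in Tregs from a change in Tconv.

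In Tregs, the effector program stood higher in KI, while no difference in Foxp3 passed. Foxp3 was 9.76 ± 0.29 in KI and 9.86 ± 0.20 in WT Tregs (SD, n = 4, difference -0.09, SE 0.154, adjusted p = 0.798). The difference was -0.11 (SE 0.209) with 2 runs and -0.25 (SE 0.245) with 3 runs as a block, and -0.32 within the arrays numbered 24 to 27. Ikzf2 (-0.07), Nrp1 (0.05), Hdac7 (0.17), Tnfrsf18 (0.22), Il2ra (0.47, adjusted p = 0.0667) and Ikzf4 (-0.45, adjusted p = 0.0721) did not pass either. The largest rise among genes without overlap was in Atp6v0d2, which encodes a subunit of the vacuolar proton pump, from 3.81 ± 0.19 to 6.02 ± 0.13 (4.61-fold, adjusted p = 4.19e-08). Its WT mean lay near background, so this fold is understated. The mitotic cyclin gene Ccnb2 rose by 2.06 (SE 0.346, adjusted p = 0.00273), Chdh by 1.52, Rapgef5 by 1.51, the hypoxia-inducible prolyl hydroxylase gene Egln3 from 5.46 ± 0.37 to 6.96 ± 0.25 (2.83-fold, adjusted p = 0.000183) and the ubiquitin ligase gene Nedd4 by 1.43.

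Apart from the transcript 3830406C13Rik (-3.82), which is described with the genes that differed in both cell types and was chosen after its values were seen, the largest falls in KI Tregs among genes without overlap were in the paraoxonase gene Pon3 (-1.53, SE 0.146, adjusted p = 9.81e-06), Rnf144a (-1.18), Arhgap5 (-1.14), Ccdc22 (-1.13, SE 0.112, adjusted p = 1.28e-05), St6galnac2 (-1.05) and Pdzk1ip1 (-1.02). In total 231 genes passed, 162 higher and 69 lower in KI Tregs, of which 114 differed by at least 1.5-fold, and 210 of the 231 did not overlap between the groups, which in genes not picked for their difference has an exact p of 0.0286. The genes listed here were picked for not overlapping.

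The effector Treg list rose in KI Tregs. Of its 20 genes 8 rose and 0 fell, or 12 and 0 adjusted over the list alone, with a mean of 0.45 (camera adjusted p = 2.59e-07, and 0.0321 with an estimated correlation). Nfil3 rose by 1.09, Prdm1, which encodes the effector regulator Blimp-1, by 0.89, the costimulatory receptor gene Icos by 0.57, and the gene of the transcription factor Batf by 0.52. Irf4 rose by 0.70 (adjusted p = 0.0432), and Gzmb and Itgae by 0.76 each. With 3 runs as a block the list kept its call (adjusted p = 4.28e-06), Nfil3 (0.0130), Icos (0.0338) and Prdm1 (0.0355) kept theirs. The calls of Gzmb and Itgae ended with differences of 0.67 (SE 0.153 before and 0.251 with the block) and 0.71 (SE 0.166 and 0.261), and those of Batf and Irf4 with smaller ones, 0.23 (SE 0.104 and 0.141) and 0.35 (SE 0.180 and 0.264). Within the arrays numbered 24 to 27 the mean of the list was 0.37, with Nfil3 at 1.33, Prdm1 at 0.91, Icos at 0.69 and Batf at 0.26.

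Both Treg lists moved further in the direction they have in Tregs. Of the 29 genes higher in Tregs 6 rose and 0 fell in KI, or 12 and 2 adjusted over the list alone, with a mean of 0.25, among them Capg (0.65) and Ctla4 (0.64, adjusted p = 0.0358). Their camera adjusted p was 0.00255, with adjusted p = 0.476 with an estimated correlation. Of the 12 genes lower in Tregs 3 fell, or 8 adjusted over the list alone, with a mean of -0.29 (adjusted p = 7.19e-09, and 0.000589 with an estimated correlation). The 3 were Tgfbr3 (-0.58), Pde3b (-0.51) and Bach2 (-0.28), a repressor gene of effector differentiation, while the survival gene Bcl2 was at -0.43 (adjusted p = 0.0611). The resting and lymphoid homing list, which shares Bach2 and Bcl2, had 1 of 8 genes lower, or 3 lower and 1 higher adjusted over the list alone (adjusted p = 0.0153, and adjusted p = 0.193 with an estimated correlation), and lost its call with 2 runs as a block, where its mean went from -0.20 to -0.14 (adjusted p = 0.243). With 3 runs as a block the lists of genes higher and lower in Tregs kept their calls (adjusted p = 3.3e-05 and 4.28e-06), and within the arrays numbered 24 to 27 their means were 0.23 and -0.21.

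Lists of metabolic and cell cycle genes stood higher in KI Tregs with the preset correlation alone. Of 16 genes of glycolysis and HIF targets 6 rose, or 8 adjusted over the list alone, among them Egln3, Tpi1 (0.42), Hif1a (0.31) and the glucose transporter gene Slc2a3 (0.30), with a list mean of 0.28 (adjusted p = 6.22e-05, adjusted p = 0.0939 with an estimated correlation, and 4.88e-06 with 3 runs as a block). Cell cycle genes had a mean of 0.71 and positive differences for 21 of 22 (adjusted p = 1.11e-08, but adjusted p = 0.476 with an estimated correlation). Over all genes 2 of them rose, Ccnb2 and Cdc20 (0.82), and 16 adjusted over the list alone, while Birc5 (2.83-fold, adjusted p = 0.0506) and the proliferation marker gene Mki67 (1.03, adjusted p = 0.058) did not pass. The cell cycle list had an adjusted p = 0.000352 with 3 runs as a block, and within the arrays numbered 24 to 27 the glycolysis and cell cycle means were 0.26 and 0.52. Oxidative phosphorylation genes had small positive differences in 25 of 26 cases (mean 0.12, adjusted p = 0.000215, and adjusted p = 0.478 with an estimated correlation), and 1, Cox5a (0.19), rose by either adjustment. Their adjusted p was 0.00545 with 3 runs as a block, and their mean within the arrays numbered 24 to 27 was 0.04.

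**Figure D2:**
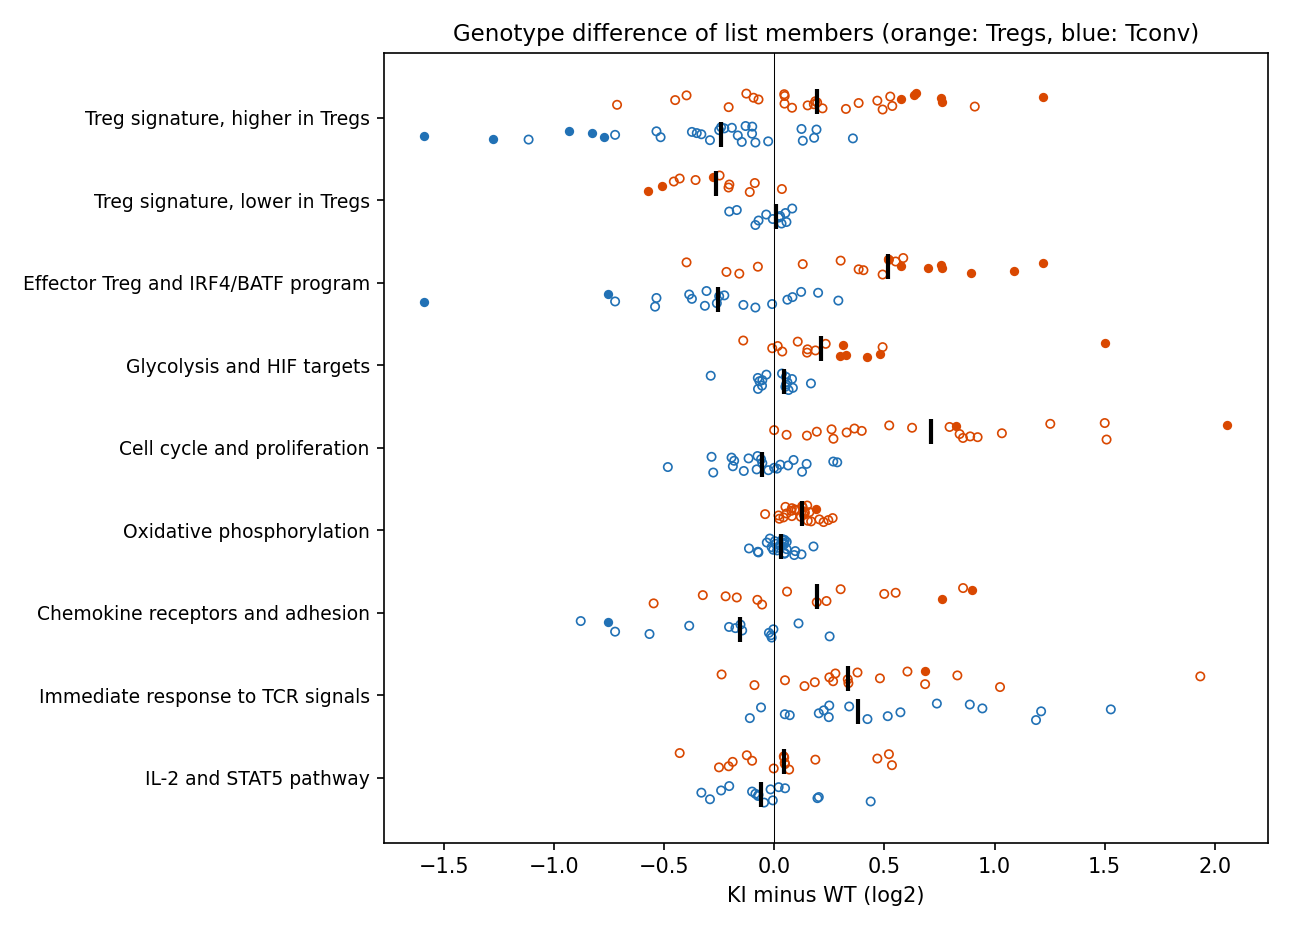
KI minus WT log2 differences of the tested genes of 9 lists in Tregs (orange) and in Tconv (blue), with filled points for genes that passed over all genes and a black bar at the median of the list. The effector Treg list had a mean of 0.45 in Tregs and -0.29 in Tconv.

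The immediate TCR response list depended on the runs. It stood higher in KI Tregs with a mean of 0.45 (adjusted p = 0.00466, and adjusted p = 0.525 with an estimated correlation), with 1 of 18 genes higher, Cd69 (0.68), or 5 adjusted over the list alone. In the fit with 3 runs as a block the list reversed (adjusted p = 0.0172), Cd69 was at -0.07, and within the arrays numbered 24 to 27 the list mean was -0.13. Fosb (1.93), Tnfaip3 (1.02) and Nr4a2 (0.68) did not pass.

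Other lists moved less in KI Tregs. Of 15 chemokine receptor and adhesion genes 2 rose, Ccr9 (0.90, adjusted p = 0.000328), which guides cells to the gut, and Itgae, or 6 adjusted over the list alone (list adjusted p = 0.192), while Ccr2 (0.86, adjusted p = 0.052) and Cxcr5 (0.50) did not pass. With 3 runs as a block the chemokine list passed with the preset correlation (adjusted p = 0.00317, against adjusted p = 0.525 with an estimated correlation and no block) and Ccr9 kept its call (0.00199). Of 24 Foxp3 partners and chromatin regulators 3 rose, Hdac9 (0.95), Hif1a and Irf4, or 4 higher and 1 lower adjusted over the list alone. Their median of 0.02 and mean of 0.06 were positive while the test pointed down (adjusted p = 0.997). Of 7 coinhibitory receptors Ctla4 rose, and Cd96 was lower as well adjusted over the list alone (list adjusted p = 0.358). None of 16 IL-2 and STAT5 genes passed over all genes by limma, with 3 higher and 1 lower adjusted over the list alone, and the test pointed down (adjusted p = 0.881) with a median and mean of 0.04. Bcl2l1 was at 0.52 and Pim1 at 0.53.

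No helper cytokine, apoptosis or interferon gene passed over all genes by limma in KI against WT Tregs. Adjusted over the list alone, 2 helper genes were higher and 1 lower of 7 (list adjusted p = 0.584), with Ifng at 1.09 (adjusted p = 0.0809) and Bcl6 at -0.27. Among 17 apoptosis genes 2 were higher and 3 lower adjusted over the list alone (adjusted p = 0.309), with Fasl at -0.52 and Tnfsf10 at -0.26. Adjusted over the list alone 0 of 16 interferon genes passed (adjusted p = 0.428), with Rtp4 at -0.35 and Zbp1 at 0.24. The neighbours of Foxp3 are given with the genes that differed in both cell types.

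Neutrophil and erythroid markers varied more within the Treg groups than between KI and WT Tregs. The neutrophil gene S100a8 ranged from 3.58 to 10.3 over the 16 arrays and the haemoglobin gene Hba-a1 from 8.20 to 12.5. Between KI and WT Tregs the neutrophil score differed by 0.74 (exact permutation p = 0.543), the B cell score by -0.22 (p = 0.8) and the erythroid score by -0.28 (p = 0.6), and the lowest exact p of the 12 scores was 0.143, for dendritic cells. By camera the adjusted p was 0.272 for B cell, 0.584 for monocyte, 0.667 for neutrophil, 0.358 for dendritic cell, 0.584 for CD8, 0.997 for NK cell, plasma cell and erythroid markers and 0.101 for heat shock genes. For plasma cell markers the test pointed down with a median of 0.30. For erythroid markers it pointed up with a median of -0.53 and a mean of -0.28, and 1 of 3, Tfrc (0.35), which T cells also express, rose by either adjustment.

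The count for KI against WT Tregs was sensitive to single arrays and to the runs. It was 101 without KI Treg 1, 106 without WT Treg 1, 126 without KI Treg 2, 130 without WT Treg 3, 139 without WT Treg 4 and 571 without KI Treg 4. It was 84 with 2 runs and 29 with 3 runs as a block, of which 73 and 27 were among the 231. With these blocks 231 and 230 of the 231 genes, which were picked on the same arrays, kept their direction. Their median difference in that direction was 0.558 and 0.515, against 0.574 without a block. Of the genes named, Atp6v0d2 (adjusted p = 0.000215), Egln3 (0.00134), Ccr9, Pon3 (0.00189), Ccdc22 (0.00428), Chdh (0.0344), Rapgef5 (0.0413), St6galnac2 (0.0413), Hif1a (0.0311) and Slc2a3 (0.0308) kept their calls with 3 runs as a block, and within the arrays numbered 24 to 27 Atp6v0d2 was at 2.08, Egln3 at 2.03 and Pon3 at -1.85. In that fit the median SE over all genes went from 0.101 to 0.148, and calls ended for genes whose difference was larger than before as well as for genes whose difference shrank. Larger, given as the log2 difference with the block and the SE without and with it, were Ccnb2 (2.38, SE 0.346 and 0.501, adjusted p = 0.0542), Arhgap5 (-1.33, SE 0.205 and 0.295, adjusted p = 0.0686), Tpi1 (0.52, SE 0.0957 and 0.138), Cdc20 (0.94, SE 0.161 and 0.237), Cox5a (0.25, SE 0.0498 and 0.0796) and Ppp1r3f (-0.78, SE 0.120 and 0.177, adjusted p = 0.0754). Somewhat smaller were Rnf144a (-1.01, SE 0.194 and 0.286), Pdzk1ip1 (-0.95, SE 0.226 and 0.309), Tgfbr3 (-0.51, SE 0.0849 and 0.113), Pde3b (-0.49, SE 0.126 and 0.202), Capg (0.58, SE 0.128 and 0.206) and Hdac9 (0.81, SE 0.179 and 0.268). Much smaller were Nedd4 (0.84, SE 0.237 and 0.327), Bach2 (-0.14, SE 0.0666 and 0.0981), Ctla4 (0.12, SE 0.158 and 0.186) and Tfrc (0.19, SE 0.0836 and 0.125). The same held for Batf and Irf4, and Cd69 went from 0.68 to -0.07. The calls of Ctla4, Irf4, Cd69, Tpi1, Tfrc, Cox5a, Bach2 and Pde3b each ended without any of at least 5 of the 8 arrays. The differences in those fits were 0.58 to 0.66 for Ctla4, 0.60 to 0.77 for Irf4 and 0.60 to 0.71 for Cd69. They were 0.36 to 0.41 for Tpi1, 0.29 to 0.38 for Tfrc and 0.16 to 0.20 for Cox5a. For Bach2 they were -0.29 to -0.24 and for Pde3b -0.51 to -0.41. The call of Gzmb ended without KI Treg 1 (0.68), and that of Itgae without WT Treg 1 (0.64) or KI Treg 3 (0.63). Calls also ended for Slc2a3 without KI Treg 1 (0.28) or WT Treg 4 (0.25), and for Pdzk1ip1 without WT Treg 2 (-0.95) or WT Treg 3 (-0.86). Genes that passed only once KI Treg 4 was left out were Bcl2 (-0.47), Bcl2l1 (0.70), Fasl (-0.62), Fosb (2.72), Gata1 (0.84), Ifng (1.28), Il2ra (0.50), Nr4a2 (0.93), Pim1 (0.63), Sdhb (0.34), Tnfaip3 (1.36) and Uqcrc1 (0.30). Without KI Treg 4 no KI Treg array shares any of the 3 runs with a WT Treg array. For these genes and the count of 571 the genotype and the runs therefore cannot be told apart. Birc5 passed without KI Treg 4 (1.68) or WT Treg 2 (1.84), Mki67 likewise (1.15 and 1.24), Tnfrsf18 without WT Treg 2 (0.28), and Ccr2 without WT Treg 3 (1.00) or KI Treg 2 (1.08).

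In Tconv, genes of Tregs were among those that fell in KI. After the transcript 3830406C13Rik (-3.64, described below and chosen after its values were seen), Klrg1 fell most, from 4.94 ± 0.44 to 3.35 ± 0.34 (SD, n = 4, difference -1.59, SE 0.232, adjusted p = 0.00332), followed by S100a4 (-1.28), Foxp3 (-0.93), Ccdc22 (-0.89), Pon2 (-0.87) and Ikzf2 (-0.83, SE 0.072, adjusted p = 5.8e-06). Nrp1 fell by 0.77 on the log2 scale (adjusted p = 0.00807). Foxp3 in Tconv lay near background, at 4.63 in WT and 3.69 in KI, so its difference understates the fold. In total 11 genes passed, 0 higher and 11 lower in KI, against 480 at an unadjusted p under 0.05 by limma, and Ctla4 (-0.19), Il2ra (-0.10), Ikzf4 (-0.35), Irf4 (0.29), Hdac7 (0.18) and Tnfrsf18 (-0.03) did not pass.

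Treg genes as a group stood lower in KI Tconv. Of the 29 genes higher in Tregs 5 fell and 0 rose, or 12 and 0 adjusted over the list alone, with a mean of -0.36 (camera adjusted p = 1.13e-15, and 0.0268 with an estimated correlation). Of 20 effector Treg genes 2 fell, Klrg1 and Ccr6 (-0.75), or 6 adjusted over the list alone, with a mean of -0.29 (adjusted p = 1.12e-07, and 0.0268 with an estimated correlation). Ccr6, a chemokine receptor gene chosen after its values were seen, was also the gene that fell of 15 chemokine receptor and adhesion genes, or 4 adjusted over the list alone (mean -0.25, adjusted p = 1.54e-05, and 0.0329 with an estimated correlation). With 3 runs as a block the list of genes higher in Tregs kept its call with a mean of -0.30 (adjusted p = 6.63e-11), and within the arrays numbered 24 to 27 its mean was -0.22. The genes lower in Tregs did not move (0 of 12 by either adjustment, adjusted p = 0.397), and their median of 0.01 and mean of -0.03 differed in sign. With 3 runs as a block the effector list kept its call (adjusted p = 6.63e-09), the chemokine list lost it with a mean of -0.13 (adjusted p = 0.128), and within the arrays numbered 24 to 27 the effector mean was -0.26.

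TCR response genes stood higher in KI Tconv (mean 0.51, adjusted p = 8.87e-08, and adjusted p = 0.215 with an estimated correlation), with 0 of 18 higher over all genes by limma and 4 adjusted over the list alone, and the direction reversed with 3 runs as a block (adjusted p = 0.2513). Apoptosis genes and B cell markers stood lower, with adjusted p of 0.032 and 0.0367, and adjusted p = 0.311 and 0.682 with an estimated correlation. Interferon genes and CD8 markers stood higher, with adjusted p of 0.0123 and 0.0367, and adjusted p = 0.631 and 0.266 with an estimated correlation. The B cell score differed by -0.47 (exact permutation p = 0.486) and the CD8 score by 0.31 (exact permutation p = 0.0571, adjusted p = 0.686). The count of 11 was 7 without KI Tconv 2, 65 without KI Tconv 4, and 7 with 2 runs and 5 with 3 runs as a block, of which 7 and 3 were among the 11 and 1 of the 5 was higher in KI. Without KI Tconv 4 no KI Tconv array shares any of the 3 runs with a WT Tconv array. With 2 runs Ikzf2, Pon2, Ccdc22 (0.0183) and Nrp1 (0.0492) kept their calls. In that fit those of S100a4 (-1.31, SE 0.227 and 0.307) and Foxp3 (-0.95, SE 0.154 and 0.209) ended at differences as large as before and wider SE, given without and with the block, and that of Klrg1 (-1.17, SE 0.232 and 0.274) at a smaller one. In the fit with 3 runs Ikzf2 (0.00276) and Pon2 (0.0364) kept theirs, and those of Ccdc22 (-0.97, SE 0.112 and 0.181) and Nrp1 (-0.66, SE 0.124 and 0.163) ended as well, with Foxp3 at -1.09 (SE 0.245). The falls of Klrg1 and S100a4 shrank there to -0.96 (SE 0.318) and -0.88 (SE 0.318), and within the arrays numbered 24 to 27 to -0.88 and -0.58. The call of Nrp1 also ended without KI Tconv 2 (-0.71), that of Foxp3 without WT Tconv 2 (-0.82), KI Tconv 2 (-0.89) or WT Tconv 4 (-0.87), and that of S100a4 without any of 6 of the 8 arrays.

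**Figure D3:**
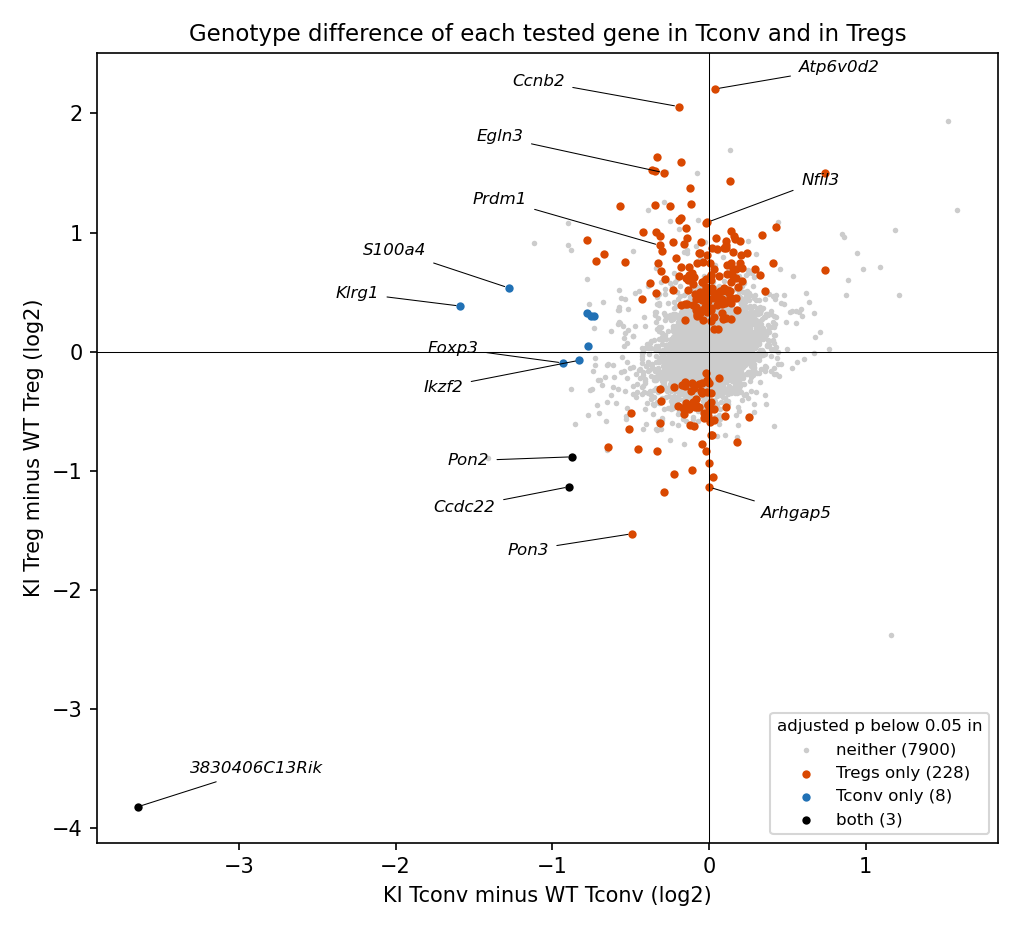
KI minus WT log2 difference of each of 8139 genes in Tconv (horizontal) and in Tregs (vertical), coloured by the cell type in which the gene passed. In both cell types 3 genes passed, all of them lower in KI.

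The effect of the genotype differed between the cell types for 64 genes, 54 with a higher and 10 with a lower KI minus WT difference in Tregs than in Tconv. The largest positive interactions were those of Ccnb2 (2.25), Atp6v0d2 (2.16, SE 0.202, adjusted p = 1.67e-05), S100a6 (2.03), Klrg1 (1.97), Chdh (1.89) and Rapgef5 (1.86). The largest negative ones were those of Pon3 (-1.04), the semaphorin gene Sema4a (-0.94), Akr1c13 (-0.93), Ms4a4c (-0.72), Crim1 (-0.72) and Tgfbr3 (-0.61). In Tconv, Pon3 (3.58 in WT and 3.09 in KI) lay near background, where a fall is understated, so its interaction does not show that the cell types differed. Atp6v0d2 (3.41 and 3.45) and Rapgef5 (4.65 and 4.30) lay near background in Tconv too, where a rise from lower levels would not be seen. Of the 231 genes that passed in Tregs 132 had the same sign in Tconv, and their median in the direction of Tregs was 0.57 in Tregs and 0.01 in Tconv.

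The Treg programs opened a wider gap between Tregs and Tconv in KI. The gap joins changes in both cell types. For the genes higher in Tregs the mean fall in KI Tconv was larger than the mean rise in KI Tregs. For the effector genes the rise in Tregs was the larger. Ikzf2 (-0.83) and Nrp1 (-0.77) fell in KI Tconv and did not pass in Tregs. The cause of the falls in Tconv stays open. Of the 29 genes higher in Tregs 8 had a positive interaction, or 18 with 1 negative adjusted over the list alone (mean 0.61, adjusted p = 2.49e-16, and 0.00937 with an estimated correlation). Of 20 effector genes 7 had a positive interaction, among them Prdm1 (1.21), Nfil3 (1.10) and Icos (0.95), or 12 adjusted over the list alone (mean 0.74, adjusted p = 2.49e-16, and 0.00179 with an estimated correlation). Genes lower in Tregs had 1 negative, or 3 adjusted over the list alone (adjusted p = 1.34e-06, and 0.00179 with an estimated correlation), and chemokine receptor genes 5 positive, or 7 adjusted over the list alone (adjusted p = 2.8e-05, and 0.0313 with an estimated correlation). Glycolysis genes had 2 positive, or 3 adjusted over the list alone (adjusted p = 5.26e-05, and adjusted p = 0.0601 with an estimated correlation), and cell cycle genes 1, or 6 adjusted over the list alone (adjusted p = 3.3e-08, and adjusted p = 0.324 with an estimated correlation). Resting and lymphoid homing (adjusted p = 0.0115), interferon (0.00705), CD8 (0.0217) and heat shock lists (0.0115) stood lower and oxidative phosphorylation genes higher (0.0079), with adjusted p = 0.125, 0.596, 0.177, 0.19 and 0.622 with an estimated correlation. The count of 64 was 37 without KI Treg 1, 42 without WT Treg 1 and 104 without KI Tconv 4, and 70 with 2 runs and 87 with 3 runs as a block. Each run holds as many Treg as Tconv arrays of a genotype, so a block leaves the interaction itself unchanged. Ccnb2 stayed at 2.25 with either block, and only its SE and p changed. The counts with blocks therefore do not test the runs. The calls of Ccnb2, Crim1, Ms4a4c, Sema4a, Pon3 and Tgfbr3 ended without any of 11, 14, 7, 6, 4 and 2 of the 16 arrays.

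A few genes were lower in KI in both cell types. The 3 that passed in both were Ccdc22, which encodes an endosomal trafficking protein, the paraoxonase gene Pon2 and the transcript 3830406C13Rik, and the last, as well as Pon2 in Tregs, was chosen after its values were seen. The transcript 3830406C13Rik lay at 6.40 ± 0.13 in WT and 2.59 ± 0.09 in KI Tregs, and at 6.33 ± 0.14 in WT and 2.68 ± 0.09 in KI Tconv (SD, n = 4), so that the KI arrays were at background. Ccdc22, the gene next to Foxp3 in assembly GRCm38.p6, lay at 9.38 ± 0.06 and 8.25 ± 0.22 in WT and KI Tregs, and at 9.14 ± 0.17 and 8.25 ± 0.20 in WT and KI Tconv. Pon2 differed by -0.88 in Tregs and -0.87 in Tconv.

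The mean of both genotype differences passed for 99 genes, 52 higher and 47 lower in KI. Of the 21 tested neighbours of Foxp3, Ccdc22 and Ppp1r3f fell in KI Tregs (-0.65 for Ppp1r3f), or 3 fell and 1 rose adjusted over the list alone, and Ccdc22 fell in KI Tconv. Over both cell types the means were -1.01 for Ccdc22 (SE 0.079), -0.58 for Ppp1r3f, -0.27 for Gpkow and 0.59 for Gata1, each of which passed. The list of neighbours had a median of 0.10 and a mean of -0.02 in Tregs (camera adjusted p = 0.881). The mean also passed for Ikzf4 (-0.40, SE 0.091, adjusted p = 0.0382), Pon3 (-1.01) and the inflammatory caspase genes Casp1 (-0.61) and Casp4 (-0.62), and both caspase genes were chosen after their values were seen.

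**Figure D4:**
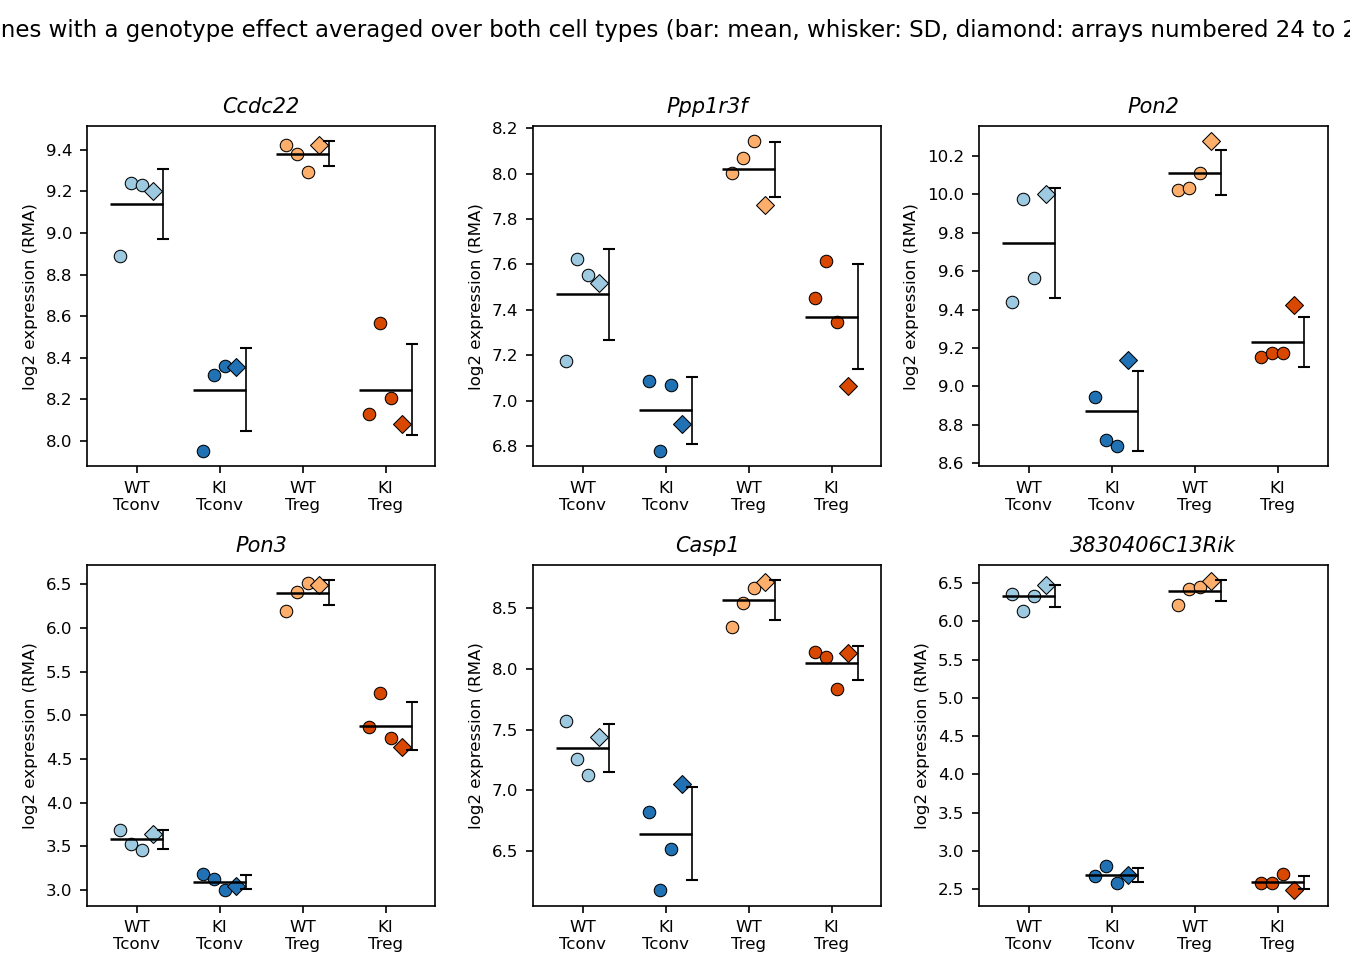
Log2 expression of 6 genes on each array in the 4 groups, with the group mean as a bar, the SD as a whisker and diamonds for the arrays numbered 24 to 27. For 3830406C13Rik the WT means were 6.33 and 6.40 and the KI means 2.68 and 2.59.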

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

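The tests of carried-over Tregs and of transgene copies, the fits of Flicr, the same-group pairs left out of the choice of genes, the list tests with runs as a block, the fits without the arrays numbered 24 to 27, the mean over both cell types with the test of neighbouring pairs, and the fits with marker scores were chosen only after the results were seen.

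Differences between KI and WT Tregs may reflect the order of processing, cells of other types in the sort, or the genotype. Of the 35 splits of the 8 Treg arrays 2 gave as many genes as the real 231, the highest other split gave 373 with KI Treg 4 exchanged for WT Treg 2, and chance was not excluded. With 2 and 3 runs as a block 73 and 27 of the 231 genes passed. In the same fits 223 and 181 stayed at an unadjusted p under 0.05 by limma in the same direction. The median differences were 0.558 and 0.515, against 0.574 without a block. The 422 genes called without the arrays numbered 24 to 27 were compared between KI Treg 4 and WT Treg 4. They differed by a median of 0.2006 in the direction of their call. This was above 0.145, the highest of 12 pairs of arrays of the same group within a run (0.172 with each pair left out of the choice of genes). As 1 array of each genotype gives no spread, this cannot exclude the runs as the whole cause. With neutrophil, erythroid and B cell marker scores as covariates, 100% of the 231 genes stayed at an unadjusted p under 0.05 by limma in the same direction. Of them 192 kept their call, and their median difference was 0.570 against 0.574 without the scores. The genes were picked on the same arrays at a stricter threshold, so most would stay in any case. This cannot decide whether such cells, which a CD3 and CD4 gate should remove, played a part. H2-Aa ranged from 7.17 to 10.3, S100a8 from 3.58 to 10.3 and Hba-a1 from 8.20 to 12.5. Of the 3 erythroid genes 1, Tfrc, is also expressed by T cells. A part played by the runs stays open, since the median of these 422 genes was 0.522 in the arrays numbered 4 to 23 they were called from. The genotype remains as an untested explanation. With 3 runs as a block Atp6v0d2, Egln3, Nfil3, Icos and Prdm1 kept their calls, while those of Batf, Irf4, Ctla4 and Cd69 ended. That fit compares the genotypes only through the arrays numbered 24 to 27, 1 of each group. Its calls therefore do not decide between the runs and the genotype.

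Treg genes lower in KI Tconv may come from Tregs left in the WT Tconv sort, from the runs, or from the genotype. Tregs carried over in bulk would need the same share for every Treg gene. Ctla4 allowed at most 1.948% on any WT Tconv array, while Ikzf2 needed 4.22%, Nrp1 4.50%, Klrg1 5.06% and S100a4 16.8%. These are genes that passed as lower in KI Tconv. Foxp3, which passed too, needed 1.28%, and the median over the 29 genes of the list was 1.82%, both below the limit of Ctla4. The shares argue against carry-over as the whole cause for Ikzf2, Nrp1, Klrg1 and S100a4, but not for the list as a whole. By camera in limma with the preset correlation, the list stood below other genes with 2 runs as a block (adjusted p = 2.98e-06, and 1.46e-07 unadjusted). It did so with 3 runs as well (adjusted p = 6.63e-11). The list means were -0.32 and -0.30, against -0.36 without a block. The fit with 2 runs pools the second and the last of the 3 runs. The fit with 3 runs compares the genotypes only through the last run, which holds 1 array of each group. A part played by the runs in the fall of the list therefore stays open. Of the 35 splits of the 8 Tconv arrays 2 gave as many genes as the real 11, the highest other split gave 59 and set WT Tconv 1, WT Tconv 2, KI Tconv 2 and KI Tconv 3 against the rest, which points to a structure among these arrays, and chance was not excluded, while with 2 and 3 runs as a block 7 and 5 genes passed, of which 7 and 3 were among the 11. A subset of Tregs low in Ctla4 and GFP in the WT sort, which the different reporters of the genotypes could produce, and an effect of the genotype on activated Tconv stay open.

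Genes lower in KI in both cell types could stem from extra gene copies on the WT transgene, from chromosome segments of another strain around or apart from Foxp3, or from the knock-in itself. Copies of the Foxp3 region on the transgene cannot be told apart from the other explanations, because the nearest tested gene on the other side of Foxp3 from Ccdc22 (-1.01), the transcript Flicr, chosen after its values were seen, lay at background in Tconv. In Tregs Flicr fell in KI, as such copies would give, by 0.62 (limma adjusted p = 0.0460). This call ended without any of 12 of the 16 arrays, with differences of -0.51 to -0.64. Leaving out a Tconv array left the difference at -0.62. The call also ended with 2 runs (-0.39) or 3 runs (-0.51) as a block, and the mean over both cell types was -0.36 (adjusted p = 0.153). Ppp1r3f, the next tested gene beyond Flicr, was at -0.65 in Tregs and -0.51 in Tconv. Plp2, the next beyond Ccdc22 and chosen after its values were seen, was at 0.06 and 0.02. Copies and a strain segment around Foxp3 could both give a fall of Ppp1r3f. The other 20 tested neighbours had a median of 0.076, with Ppp1r3f (-0.58), Gpkow (-0.27) and Gata1 (0.59) passing, and among 41 genes with an effect in both cell types, 3 pairs were neighbours, Pon3 with Pon2 on chromosome 6, Casp1 with Casp4 on chromosome 9 and Ppp6c with Arhgap15 on chromosome 2 (the last pair chosen after its values were seen), against a mean of 0.206 pairs in 10000 random sets (permutation p = 0.001). That is consistent with linked strain segments, but shared control of related neighbours such as both paraoxonase and both caspase genes, and the genotype, stay open.

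For WT Tregs against WT Tconv 1 of the 35 splits, the real one, gave as many as 2818 genes and the highest other gave 0, and for KI Tregs against KI Tconv 1 of 35 gave 3343 and the highest other gave 1. This is the smallest share that 35 splits allow. Every other split mixes Tregs with Tconv, which widens the spread, so the counts of 0 and 1 do not tell how many genes chance would give. For the interaction 2 of 100 draws of genotype labels within the cell types, the real labels included, gave at least 64 genes. This share was under the limit set beforehand. The highest other draw gave 719, far more than the real labels, which points to a structure among the samples, so chance was not excluded.

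The test of the difference itself found 64 genes whose genotype effect differed between the cell types. Among the named genes the interaction was positive for Ccnb2 (2.25), Atp6v0d2 (2.16), S100a6 (2.03), Klrg1 (1.97), Chdh (1.89), Rapgef5 (1.86), S100a4 (1.81), Egln3 (1.79), Ccr2 (1.74), Itgae (1.49), Gzmb (1.29), Prdm1 (1.21), Nfil3 (1.10), Icos (0.95), Nrp1 (0.82), Ccr9 (0.79), Ikzf2 (0.75) and Hif1a (0.39). Of these, Atp6v0d2, Klrg1, Rapgef5, Egln3, Itgae, Gzmb and Nfil3 had means under 5 in both Tconv groups, near background. It was negative for Pon3 (-1.04, at background in Tconv, where a fall is understated, so that no difference between the cell types is shown), Sema4a (-0.94), Akr1c13 (-0.93), Ms4a4c (-0.72), Crim1 (-0.72) and Tgfbr3 (-0.61).

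In 18 of 480 groups of 4 arrays, over 120 named genes, and in 4 of 108 groups of list means, over 27 lists, 1 array lay far from the other arrays of its group by Dixon's test, which chance gives in about 1 in 20 groups. KI Tconv 4 stood apart for Ctla4 (5.67), Klrg1 (3.85), Nedd4 (4.305), Tgfbr3 (10.9) and Tnfaip3 (8.98). KI Treg 4 stood apart for Bcl2l1 (6.92), Fasl (5.68), Pon2 (9.425) and Tpi1 (8.36). WT Treg 4 did so for C1qa (7.15), Rnf144a (6.24) and Slc2a3 (10.6), and WT Tconv 4 for Ctla4 (6.81). These 4 arrays form the last of the 3 runs. They stood apart 5 (KI Tconv 4), 4 (KI Treg 4), 3 (WT Treg 4) and 1 (WT Tconv 4) times, all for genes. Among the other arrays, the highest count was 3, for WT Tconv 3. The chance rate does not cover how the outliers fall on the arrays, so a part played by the runs stays open. WT Tconv 3 stood apart for Ikzf2 (8.91), Nkg7 (6.52) and the mean of genes higher in Tregs (5.99). The remaining arrays were WT Tconv 1 for Ccdc22 (8.89), KI Tconv 1 for Ccdc22 (7.95) and the heat shock mean (9.00), KI Treg 2 for Rapgef5 (7.44), and WT Treg 2 for the coinhibitory mean (9.54) and the oxidative phosphorylation mean (10.2).

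Probe sets with no listed gene, which the comparisons leave out, also differed. Of 15588 such probe sets 5359 passed the expression filter, and 55 of them differed between KI and WT Tregs, 20 higher and 35 lower in KI, and 3 between KI and WT Tconv, all lower. The largest difference in both, beyond that of any tested gene, was that of the same probe set, at 8.55 ± 0.12 in WT and 3.37 ± 0.18 in KI Tregs and at 8.38 ± 0.09 in WT and 3.36 ± 0.36 in KI Tconv (SD, n = 4). It was chosen after its values were seen, and it fell in KI by 5.19 in Tregs and 5.01 in Tconv, with the KI arrays at background.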

How the results depend on the processing

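Fits without the arrays numbered 24 to 27, fits with marker scores and list tests with runs as blocks were chosen only after the results were seen. No paired analysis was possible because the title numbers are not shared between groups. At 1.5-fold as well, 1098, 1301 and 114 genes passed between WT cell types, between KI cell types and between KI and WT Tregs, fewer by construction. For KI against WT Tregs (231), the filter at log2 7, which tests fewer genes, gave 138, array weights 1715, the blocks of 2 and 3 runs 84 and 29, the random block 130, the fit without the arrays numbered 24 to 27 gave 422 and marker scores 418. For KI against WT Tconv (11), array weights gave 249, the blocks of 2 and 3 runs 7 and 5 (7 and 3 of them among the 11), a fit of both groups alone 4, the fit without those arrays 105 and marker scores 19. Array weights gave 453 for the interaction (64). Leaving out 1 array gave 2443 to 2675 and 2890 to 3344 between the cell types in WT and KI, 101 (without KI Treg 1) to 571 (without KI Treg 4) between Tregs, 7 (without KI Tconv 2) to 65 (without KI Tconv 4) between Tconv, and 37 (without KI Treg 1) to 104 (without KI Tconv 4) for the interaction, with 106, 126, 130 and 139 between Tregs without WT Treg 1, KI Treg 2, WT Treg 3 and WT Treg 4, and 42 for the interaction without WT Treg 1. The ratio of KI to WT differences for genes lower in Tregs went from 1.09 to 1.05 with selection at 1.5-fold. It was 0.998 without the arrays numbered 24 to 27, where genes were also selected on 1 WT array of each cell type instead of 2. Leaving out 1 KI array gave 1.07 to 1.10, and 1.19 to 1.26 for genes higher in Tregs, and no WT array was left out. With 3 runs as a block Cd69 reversed in KI against WT Tregs (-0.0712), as did the TCR response list in Tregs (adjusted p = 0.01723) and in Tconv (adjusted p = 0.2513). Except where fewer genes or samples were tested, the cause was not tested. For 165 results of named genes, 3682 alternatives left 3305 in the same direction and on the same side of the threshold, or within the spread where untested, while 218 lost a call, 90 gained one, 68 moved and 1 reversed. For 125 list results these were 598, 63, 32, 55 and 2 of 750. Genes such as Foxp3, Klrg1 and Pon3 in Tconv lay near background, where differences are understated.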
